A study of Homo sapiens with 20 samples.

How the data were processed

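Total RNA from 20 cultures of primary human mammary epithelial cells, 10 per virus, was measured with 1-colour Affymetrix expression arrays after one-cycle in vitro transcription and biotin labelling, per the labels' protocols. Each array was assigned to 2x9 or L2L3M by its title. In the source description of 1 array, 2x9 replicate 10, the variant name carries another number than in its title. Its group thus rests on the title, and the counts of genes, the gene lists and the named genes were also computed without it. The labels call the replicates independent and biological, and they say that the 2 variants reached comparable protein levels on western blots. They do not say whether the cultures came from 1 donor or several, so p-values measure the spread between these cultures.

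The values used are those the authors deposited, 1 per probe set and array, on a log2 scale. The probe set summary, background correction and normalization are not given in the sources used here. The base of the log is inferred from the values, which run from 0 to 13.6: as natural logs they would exceed the range of a 16-bit scanner. The values have 2 decimals and a floor at 0, where each array had between 57 and 87 probe sets and where 637 probe sets stood on at least 1 array. Array medians lay between 6.29 and 6.41, lower quartiles between 4.01 and 4.19 and upper quartiles between 8.71 and 8.82. Sorted values differed between arrays by up to 0.36, so the deposited probe set values do not share 1 distribution. Whether a common distribution was set before the probes were summarized is not known here. No 2 arrays held identical values. The mean 3' minus 5' difference of the beta-actin control probe sets was 0.05 ± 0.05 in 2x9 and 0.08 ± 0.03 in L2L3M (SD, n = 10 each), and that of the GAPDH control -0.01 ± 0.03 and -0.04 ± 0.05. Control probe sets for a bacterial trp gene, with means of 3.44, 3.05 and 3.95, served as a reference for background; detection calls were not used here.

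Probe sets were named from the platform annotation. Of 22277 probe sets 19730 had 1 gene symbol, 568 had several and 1979 had none here, and only the first kind were named. Symbols were checked against a RefSeq gene table (assembly GRCh38.p14, used for names and gene order only) through their Entrez numbers: 19713 probe sets matched, 17 kept the symbol of the annotation and 0 changed. Each of 12165 genes was represented by the probe set with the highest mean over the 20 arrays. Genes of the Y chromosome and XIST entered the counts and are not named. Some probe sets may read transcripts of close relatives.

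The groups were compared with limma (version 3.58.1, R 4.3.3) using lmFit and eBayes on the log2 values, two-sided, with no filter on dim genes and no block; p-values were adjusted by Benjamini-Hochberg over all genes, at a threshold of 0.05. Genes changed at least 1.5-fold were counted as well. The 31 gene lists held 709 genes, of which 613 were measured, and 2 outdated symbols were renamed. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry, which asks whether members move one way on balance and does not compare a list with other genes. The named genes were fixed by a rule: PPARGC1A, ESRRA, ESRRB and ESRRG, the 10 largest rises and 10 largest falls among called genes, and from each list the 2 members with the largest absolute moderated t. The groups, gene lists, rule and first alternatives were fixed before the data were examined.

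The alternatives were a replicate block, quantile normalization, median centring, the mean of all probe sets of a gene, leaving out probe sets with the suffixes _x_at and _s_at, leaving out the lowest 25% or 50% of genes by level, trended and robust eBayes, array weights, an adjusted p under 0.01, and leaving out each array in turn. Chosen after seeing the data were a block for 4 sets of arrays, leaving out both arrays numbered 5, leaving out each array for the inflammatory list, and testing each probe set by itself. The array sets came from hierarchical clustering of deviations from the group means over 6066 genes above the median level, without the inflammatory list. A further 40 cell cycle genes outside the fixed list were chosen after seeing the data, and 38 were measured. Chance was assessed with 100 splits of the arrays into 10 and 10, the real one included. Outlying arrays were sought with Dixon's ratio at a critical value of 0.466.

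The steps were tested on simulated data with the spread of the real arrays and 12165 genes. Each gene was drawn independently, without the correlation between genes or the array sets of the real data. The rates below hold for that setting and need not hold for the real arrays. A log2 change of 0.25 was recovered for 34.3% of changed genes and for 55.0% among genes above the median level, a change of 0.5 for 67.2% and 95.0%, and a change of 1 for 83.3% and 100.0%. Of the calls 3.77% were false. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.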

Results

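Gene expression was profiled in primary human mammary epithelial cells infected with an adenovirus carrying 1 of 2 engineered variants of PGC-1alpha, a transcriptional coactivator that binds nuclear receptors. The variant 2x9 acts through the orphan nuclear receptor ERR-alpha, the product of ESRRA, whereas the variant L2L3M has no working receptor-binding box and serves as the control. Per the labels, cells were starved of serum for 36 h, infected at a multiplicity of 150 and harvested 16 h later, and each virus was represented by 10 independent biological replicates, each on its own array. Cells without virus were not analysed here, so each difference is between the 2 variants. The deposited log2 values had a mean array median of 6.37 ± 0.04 (SD, n = 10) for 2x9 and 6.35 ± 0.03 (SD, n = 10) for L2L3M, and any 2 arrays correlated across probe sets with r between 0.959 and 0.979. The number of arrays limits the precision of each difference.

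The comparison of 2x9 with L2L3M asks which genes respond when ERR-alpha is engaged by its coactivator. Genes of mitochondrial energy metabolism rose together in 2x9 cells, from the respiratory chain and the tricarboxylic acid cycle to fatty acid oxidation and mitochondrial protein import. The largest measured rises were in single genes of varied function, among them PPP1R3C, a subunit that targets a phosphatase to glycogen, which was 14.2-fold higher (log2 fold change 3.83 ± 0.09, SE, n = 10 per group). A set of inflammatory genes including IL1B and CXCL1 fell. Of 12165 genes tested with limma, 1113 were higher and 406 lower in 2x9 at a Benjamini-Hochberg adjusted p under 0.05, and 267 and 33 of these differed at least 1.5-fold. The share of higher genes among the calls was 73.3%, and it was 59.3% after quantile normalization, which left the share among calls of at least 1.5-fold at 88.7% against 89.0% as deposited.

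**Figure D1:**
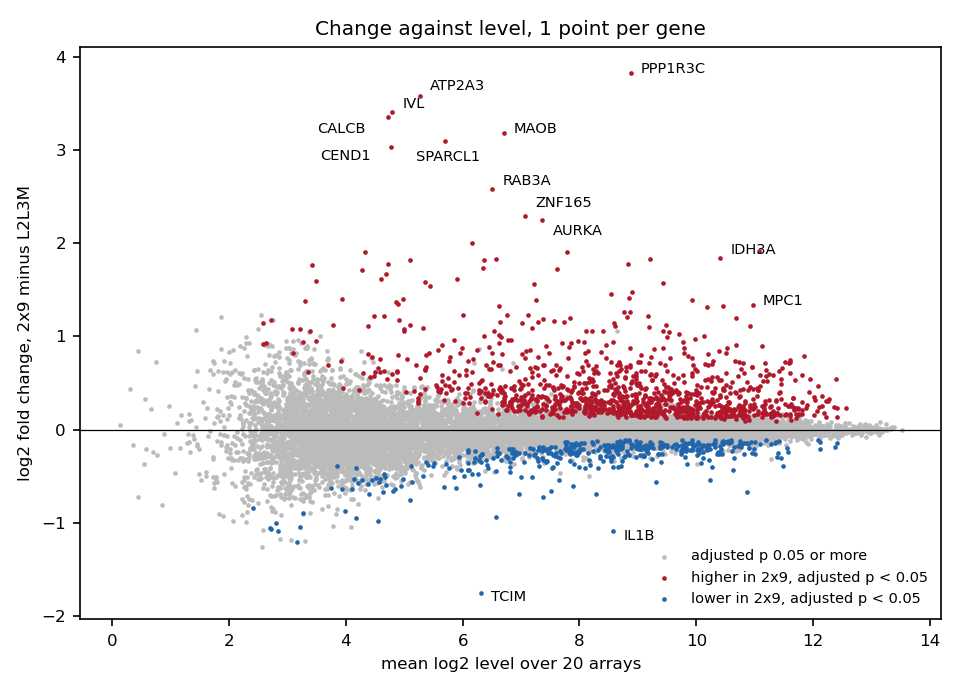
Each point is 1 gene, with its mean log2 level over the 20 arrays on the horizontal axis and the log2 fold change of 2x9 minus L2L3M on the vertical axis. Red points are the genes called higher and blue points those called lower at an adjusted p under 0.05; the named points reach from PPP1R3C at 3.83 down to TCIM at -1.76.

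ESRRA itself rose in 2x9. Its brighter probe set went from a log2 level of 8.71 ± 0.21 (SD, n = 10) in L2L3M to 9.25 ± 0.18 (SD, n = 10) in 2x9, a fold of 1.46 (limma adjusted p = 0.000124). Its dimmer probe set rose as well, by 5.22-fold (limma adjusted p = 1.50e-08), from a level of 4.76 ± 0.55 to 7.14 ± 0.32 (SD, n = 10 each). The 2 probe sets thus differ in the size of the rise. The size of that second rise is uncertain, because 4.76 lies within the range of single readings of the array's probe sets for a bacterial trp gene, 1.49 to 5.23. ESRRB and ESRRG, the related receptors, had log2 fold changes of 0.29 ± 0.34 and 0.09 ± 0.26 (SE), which did not pass the test (adjusted p = 0.699 and 0.898). In 2x9 and L2L3M, ESRRB read 3.4 and 3.1 and ESRRG 4.2 and 4.1, all within that bacterial range. These probe sets therefore do not show whether either receptor was expressed or changed. PPARGC1A, the gene both viruses carry in altered form, read 3.58 ± 0.58 in 2x9 and 3.32 ± 0.83 in L2L3M (SD, n = 10 each; adjusted p = 0.691). Those readings lie among the bacterial probe sets, whose means ran from 3.05 to 3.95. Whether the PPARGC1A probe set matches the part of the transcript carried by the viruses is not known here, so it does not check the labels.

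The other genes among the 10 largest measured log2 fold changes included ATP2A3, a calcium pump of the endoplasmic reticulum (12.0-fold), IVL, the cornified envelope protein involucrin (10.6-fold), CALCB, a calcitonin gene-related peptide (10.3-fold), and MAOB, a monoamine oxidase of the outer mitochondrial membrane (9.10-fold). SPARCL1, CEND1, RAB3A, ZNF165 and AURKA were higher by 8.59-fold, 8.16-fold, 5.98-fold, 4.92-fold and 4.74-fold. For all 10 genes every 2x9 array lay above every L2L3M array, and the limma adjusted p was 5.32e-08 or smaller. In L2L3M cells 7 of the 10 had mean log2 levels within the range of single bacterial readings: ATP2A3 at 3.47, IVL at 3.09, CALCB at 3.04, CEND1 at 3.26, SPARCL1 at 4.15, MAOB at 5.11 and RAB3A at 5.22. Their folds start from values not shown to be above background, so neither the size of these folds nor the order among the 10 is established. PPP1R3C, ZNF165 and AURKA lay above that range in both groups. Without probe sets that may match several transcripts, AURKA was read by its dimmest probe set alone, at a log2 fold change of 0.91 and an adjusted p of 0.0622.

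The largest falls were smaller. TCIM, a regulator of Wnt signalling, dropped from 7.18 ± 0.55 to 5.43 ± 0.47 (SD, n = 10 each), 3.38-fold lower in 2x9 (limma adjusted p = 6.47e-06). IL1B, the cytokine interleukin-1 beta, was 2.13-fold lower (adjusted p = 0.000966). The other 8 of the 10 largest falls were HAO1, GZMH, EDDM3B, OR7C2, GCM2, FPR3, SERPINA2 and CD207. Their mean levels lay between 2.17 and 5.03 in both groups, within the range of single bacterial readings. Neither the falls nor their size is therefore established, since these probe sets do not show whether the 8 genes were expressed. Several of them lost their call under other settings, and GZMH had an adjusted p of 0.105 without both arrays numbered 5.

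**Figure D2:**
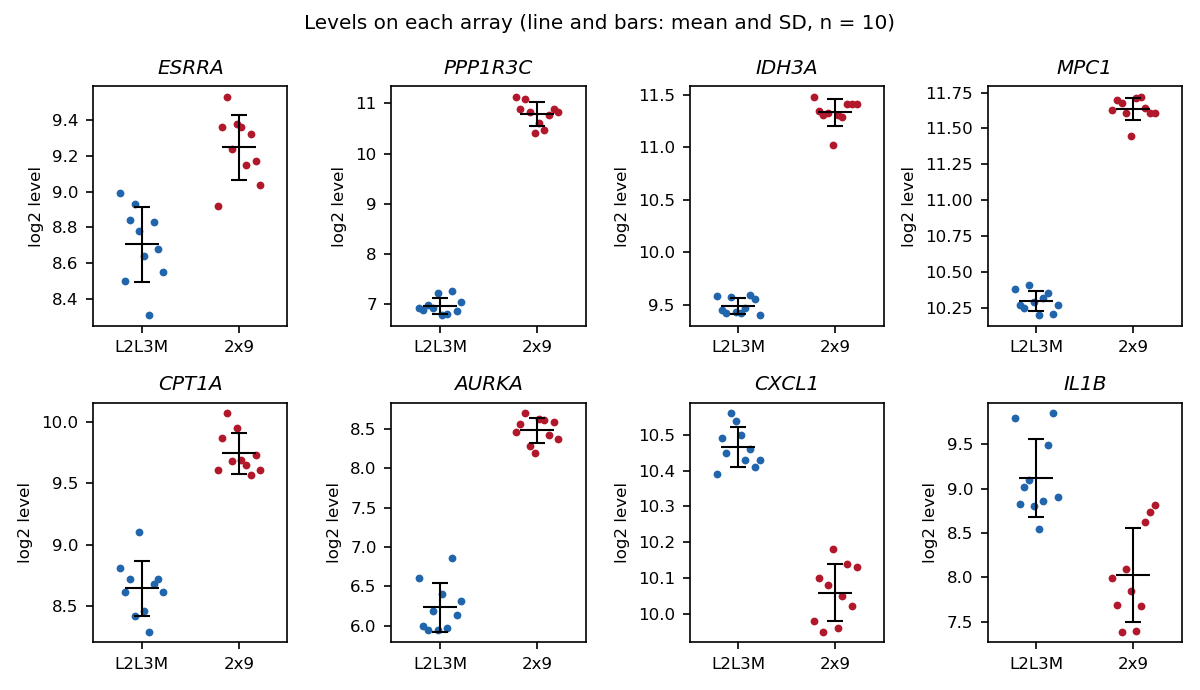
Each point is the log2 level of the named gene on 1 array, with L2L3M in blue and 2x9 in red, and the line and bars give the mean and SD of 10 arrays. For PPP1R3C, IDH3A, MPC1, CPT1A and AURKA all 10 arrays of 2x9 lie above all of L2L3M, for CXCL1 all 10 lie below, and for ESRRA 9 and for IL1B 7 arrays of 2x9 lie outside the L2L3M range.

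Subunits of the respiratory chain rose almost throughout. Of 31 measured complex I subunits, 28 rose and none fell, with a median log2 fold change of 0.30 (camera adjusted p = 2.18e-31, or adjusted p = 0.000436 with an estimated correlation), and adjusted over the list alone 30 rose. NDUFA8 was 1.88-fold and NDUFS3 1.77-fold higher. Of 23 genes of complexes II to IV and cytochrome c, 22 rose and none fell, with a median of 0.36 (camera adjusted p = 7.86e-34, or adjusted p = 4.20e-05 with an estimated correlation; 23 rose adjusted over the list alone). Examples were SDHD, a membrane anchor of complex II, at 1.65-fold, and COX5A, a subunit of complex IV, at 1.58-fold; a second COX5A probe set at the level of the bacterial ones, 3.14 against 3.23, did not follow. Of 20 genes of ATP synthase and adenine nucleotide exchange, 17 rose and none fell, with a median of 0.40 (camera adjusted p = 2.16e-25, or adjusted p = 0.000214 with an estimated correlation; 17 rose adjusted over the list alone). SLC25A5, which exchanges ADP for ATP across the inner membrane, was 1.72-fold and ATP5PO 1.45-fold higher.

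In the lists of fuel metabolism rises outnumbered falls. In the tricarboxylic acid cycle 15 of 17 genes rose, with a median of 0.38 (camera adjusted p = 9.25e-23, or adjusted p = 0.000371 with an estimated correlation; 15 rose adjusted over the list alone), led by IDH3A, the catalytic subunit of NAD-dependent isocitrate dehydrogenase, at 3.59-fold (log2 levels 11.33 ± 0.12 and 9.49 ± 0.08, SD, n = 10 each), and SUCLG1 at 1.65-fold. In fatty acid oxidation 15 of 21 genes rose, with a median of 0.17 (camera adjusted p = 4.03e-09, or adjusted p = 0.00247 with an estimated correlation; 15 rose adjusted over the list alone); CPT1A, which commits fatty acids to mitochondrial import, was 2.15-fold and ACADM, the medium-chain dehydrogenase, 1.70-fold higher. Among 9 genes of pyruvate handling 4 rose, MPC1, LDHB, MPC2 and PDP1, and none fell, with a median of 0.23 (camera adjusted p = 0.000524, or adjusted p = 0.00442 with an estimated correlation; 5 rose adjusted over the list alone). MPC1, a subunit of the carrier that brings pyruvate into mitochondria, was 2.53-fold higher. In glycolysis 8 of 17 genes rose and 1, PFKFB3, fell, with a median of 0.21 (camera adjusted p = 2.60e-05, or adjusted p = 0.0305 with an estimated correlation; 8 rose and 1 fell adjusted over the list alone); GPI and PFKM were 1.79-fold and 1.76-fold higher. In the breakdown of branched-chain amino acids 7 of 19 genes rose and none fell, with a median of 0.10 (camera adjusted p = 0.00194), and adjusted over the list alone 7 rose and 2 fell. The call was lost with an estimated correlation (adjusted p = 0.0658). AUH was 1.64-fold and MMUT 1.42-fold higher.

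Genes that build and maintain mitochondria rose in part. Of 21 genes of protein import and folding 16 rose, with a median of 0.33 (camera adjusted p = 8.57e-15, or adjusted p = 0.000176 with an estimated correlation; 16 rose adjusted over the list alone), among them TIMM8A at 2.02-fold and TIMM17A at 1.43-fold. Of 46 genes of the mitochondrial ribosome 19 rose and 27 did not pass, with a median of 0.12 (camera adjusted p = 1.95e-12, or adjusted p = 0.0356 with an estimated correlation; 22 rose adjusted over the list alone), and MRPL34 and MRPL15 were 2.30-fold and 2.15-fold higher. Of 23 genes of mitochondrial DNA upkeep, transcription and dynamics 8 rose and 1, GABPB1, fell, with a median of 0.09 (camera adjusted p = 0.000295, or adjusted p = 0.0331 with an estimated correlation; 10 rose and 1 fell adjusted over the list alone). CHCHD3, which shapes the cristae, was 1.66-fold and MFN2, which fuses outer membranes, 1.54-fold higher. Of 13 genes of redox defence and uncoupling 5 rose, NNT, SOD2, TXN2, GSR and GPX1, with a median of 0.06 (camera adjusted p = 0.00383; 5 rose adjusted over the list alone). That call was lost with an estimated correlation (adjusted p = 0.0560). NNT, the nicotinamide nucleotide transhydrogenase, was 1.83-fold and SOD2 1.55-fold higher.

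Of 28 measured genes described as targets of ERR-alpha or PGC-1alpha 19 rose and none fell, with a median log2 fold change of 0.47 (camera adjusted p = 2.05e-21, or adjusted p = 3.51e-05 with an estimated correlation; 20 rose adjusted over the list alone). Of these 28 genes 23 also belong to another of the lists, IDH3A and ACADM among them, and of the 5 that belong to no other list 4 rose. Of 13 PPAR target genes 4 rose, CPT1A, SLC25A20, PLIN2 and ACADVL, and none fell, and the list was not called (median 0.31, camera adjusted p = 0.0575; 4 rose adjusted over the list alone). That outcome held in 5 of 12 alternatives, and the list was called higher in the others.

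Inflammatory genes went the other way. Of 22 measured inflammatory and NF-kappaB genes 10 fell and 1 rose, with a median log2 fold change of -0.20 (camera adjusted p = 7.57e-05, or adjusted p = 0.00508 with an estimated correlation; 10 fell and 2 rose adjusted over the list alone). CXCL1, a neutrophil-attracting chemokine, was 1.33-fold lower, at 10.06 ± 0.08 in 2x9 and 10.47 ± 0.06 in L2L3M (SD, n = 10 each). SOD2, the mitochondrial superoxide dismutase, which this list shares with the redox list, was the gene called higher over all genes. CCL2, another chemokine, had the largest positive log2 fold change of the list, 1.055, but did not pass over all genes (limma adjusted p = 0.0639). CSF3 stood at 0.64 and was not called over all genes either. None of 26 interferon response genes was called in either direction by limma, and none had an unadjusted p under 0.05 (0; camera adjusted p = 0.613, fry adjusted p = 0.679); IRF9 and OASL had log2 fold changes of 0.12 ± 0.07 and 0.32 ± 0.19 (SE). Of 19 estrogen receptor target genes 3 fell, SIAH2, XBP1 and CCND1, with a median of -0.10 (camera adjusted p = 0.0467; 4 fell adjusted over the list alone). That call was lost with an estimated correlation (adjusted p = 0.125).

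Members of the nuclear receptor list went both ways, 5 up and 5 down of 32 (median -0.01, mean 0.07, camera direction lower, adjusted p = 0.949; 6 and 6 adjusted over the list alone). RARB, a retinoic acid receptor, was 3.07-fold higher, from an L2L3M level of 5.09 that lies within the bacterial range, and NCOA1, a coactivator, 1.26-fold higher; the other 3 that rose were ESRRA, NR2F6 and NR1H3, and ESR2, RARG, RXRA, VDR and NR3C1 fell. In the cell cycle list 5 of 28 genes rose and 3 fell, and the list was not called (median 0.03, camera adjusted p = 0.335; 5 rose and 4 fell adjusted over the list alone). The 5 were AURKA, a mitotic kinase, CCNE1, a cyclin of the G1/S transition at 1.85-fold, MCM4, CENPF and MCM3, and the 3 were CCNE2, CCND1 and MCM6. In the epidermal differentiation list IVL and KRT10 alone rose among 21 genes (median -0.14, mean 0.04, camera direction lower, adjusted p = 0.615; 2 rose adjusted over the list alone), KRT10 by 1.12-fold.

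The remaining lists were not called. Among hypoxia-inducible genes ADM, VEGFA and EGLN1 rose and MXI1 fell, of 14 (median 0.01, camera adjusted p = 0.441; 3 rose and 1 fell adjusted over the list alone), with ADM at 1.27-fold. Among 15 p53 target genes GDF15, TNFRSF10B and SESN1 rose and PLK3 fell (median 0.04, camera adjusted p = 0.543; 3 rose and 2 fell adjusted over the list alone), with GDF15, a stress-induced cytokine, at 2.48-fold. Among 23 genes of the unfolded protein and amino acid stress response DDIT3 rose and CHAC1, XBP1, HERPUD1 and VLDLR fell (median -0.06, camera adjusted p = 0.0570; 1 and 4 adjusted over the list alone). In fatty acid synthesis ELOVL6 rose and ACLY fell, of 10 genes (median -0.07, camera adjusted p = 0.535; 1 and 1 adjusted over the list alone), and in cholesterol synthesis EBP rose, of 16 (median 0.05, camera adjusted p = 0.518; 1 adjusted over the list alone), while DHCR7 had a log2 fold change of 0.39 ± 0.13 (SE, adjusted p = 0.0564). Genes named beyond the fixed rule for examples were chosen after their values were seen.

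Markers of cell identity differed little. Among 14 basal mammary markers ITGB4 fell, by 0.15 on the log2 scale (list median -0.03, camera adjusted p = 0.0650; 1 adjusted over the list alone), and SFN had a log2 fold change of -0.08 ± 0.03 (SE). Further ITGB4 probe sets stood at -0.27, -0.46 and, within the bacterial range, -0.02. Of 19 luminal markers 0 were called by limma and 4 had an unadjusted p under 0.05 (median 0.00, mean 0.06, camera direction lower, adjusted p = 0.951, fry adjusted p = 0.698), KRT8 and GATA3 standing at -0.13 and -0.15. Of 22 fibroblast and mesenchymal markers SNAI2 fell, by 0.18 (median -0.05, camera adjusted p = 0.232; 0 adjusted over the list alone), and COL1A1 stood at -0.26 ± 0.11 (SE). The probe sets of COL1A1 disagreed: a dimmer one rose by 0.36 (limma adjusted p = 0.0383, each probe set by itself). Those at -0.37 and -0.06 were not called. Of 15 immune and 11 endothelial markers 0 were called by limma, with 2 at an unadjusted p under 0.05 in each list (medians -0.15 and 0.11, camera adjusted p = 0.398 and 0.543, fry adjusted p = 0.270 and 0.0429). ITGAM and CSF1R had log2 fold changes of -0.68 ± 0.23 and -0.29 ± 0.12, and KDR and FLT1 of 0.64 ± 0.21 and 0.59 ± 0.25 (SE). ITGAM, KDR and FLT1 read within the range of single bacterial readings in both groups, so these differences are uncertain. A second ITGAM probe set, also in that range, stood at 0.34 and was not called. Of 43 cytosolic ribosomal protein genes 0 were called by limma and 1 had an unadjusted p under 0.05 (median 0.00, camera direction lower, adjusted p = 0.904, fry adjusted p = 0.884), with RPS16 at 0.06 ± 0.02 and RPL8 at 0.05 ± 0.03 (SE).

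**Figure D3:**
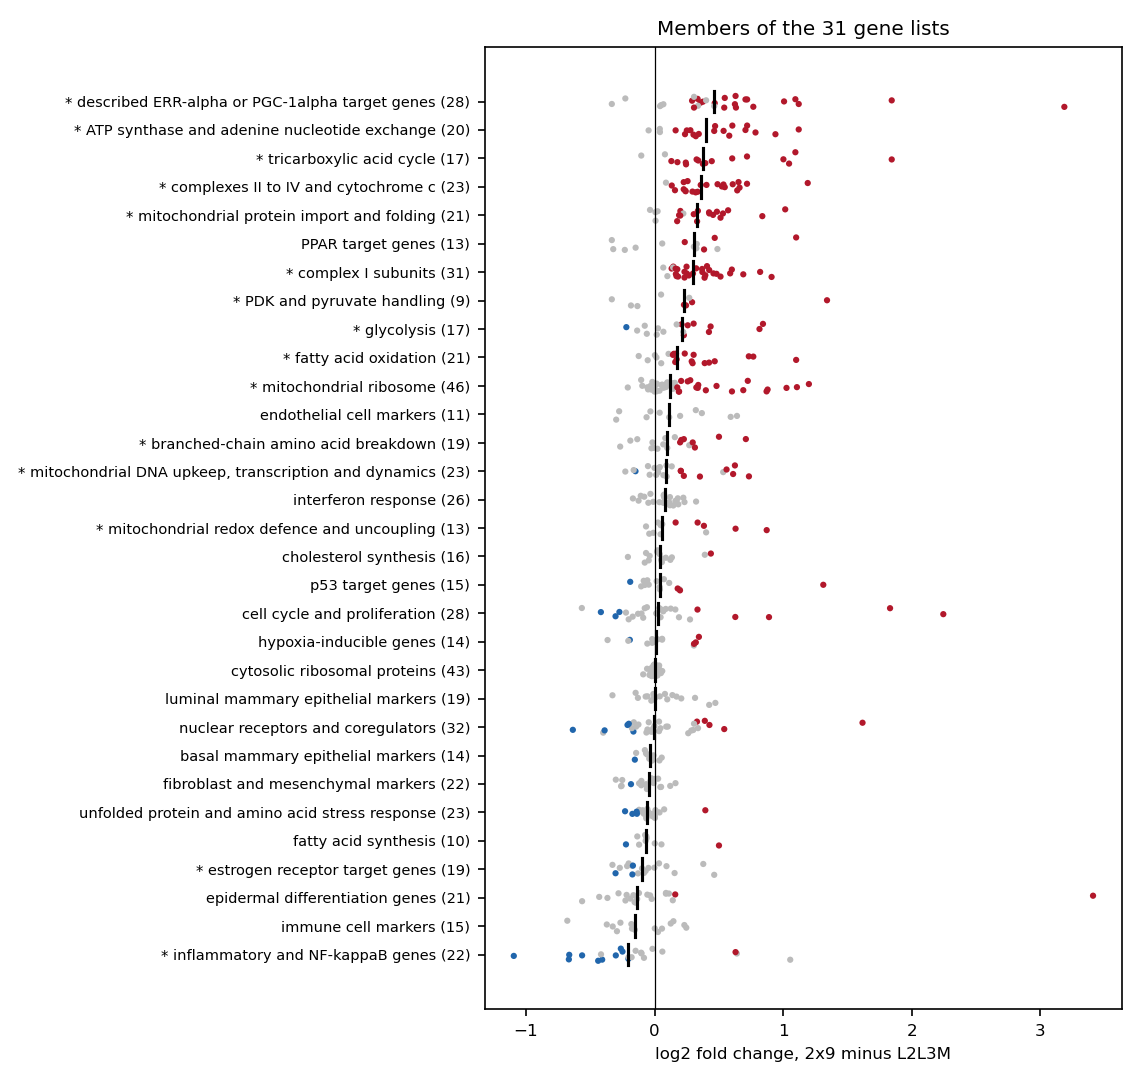
Each point is the log2 fold change, 2x9 minus L2L3M, of 1 measured member of the list named on the left, with the number measured in brackets; red and blue points were called higher and lower at an adjusted p under 0.05, the black bar is the median and an asterisk marks the 15 lists called by camera. The medians run from 0.47 for described ERR-alpha or PGC-1alpha targets to -0.20 for inflammatory genes.

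In all, 15 of the 31 lists were called with the preset correlation, 13 higher and 2 lower, and 12 of them also with an estimated correlation. Clustering of the deviations from the group means gave 4 sets of arrays, each holding both viruses. The median correlation of a 2x9 with an L2L3M array was 0.29 within a set and -0.12 between sets, a contrast that the clustering itself favours. When each gene's deviations were permuted separately within the groups and the arrays clustered again, the within-set median was at most 0.0241 in 100 permutations. That permutation also removed the correlation between genes, which by itself brings such values near 0. It therefore does not show that the sets go beyond what the clustering favours. Within the sets the median of the inflammatory list was -0.23, -0.23, -0.19 and -0.28, and that of complex I 0.34, 0.26, 0.29 and 0.32. With the array set as a block, chosen after seeing the data, 1405 genes were higher and 795 lower. The sets came from deviations of these same values, which the block then takes out, so its p-values may be too small.

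**Figure D4:**
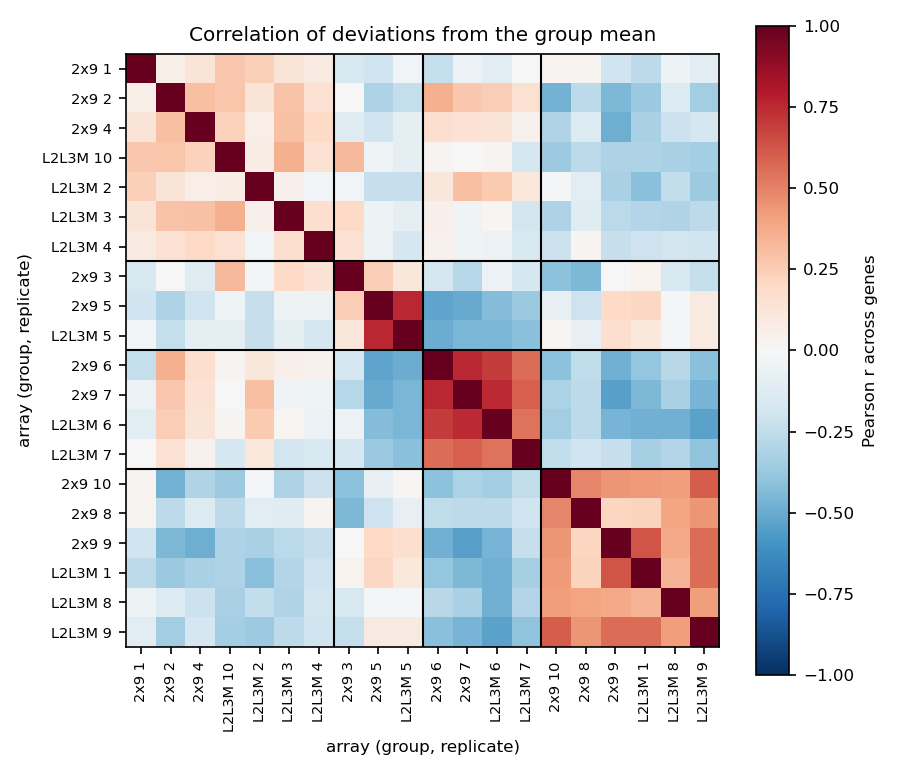
Each cell gives Pearson's r, across genes above the median level, between 2 arrays after the mean of each group was taken off; rows and columns are the 20 arrays by group and replicate, and black lines part the 4 sets. The 4 arrays numbered 6 and 7 form the tightest set, with a median r of 0.65 between groups.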

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

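The tests of the normalization, of cycling cells, of other probe sets, of neighbouring genes, of array sets, of single arrays and of the interferon list were chosen after the patterns they bear on were seen, and so was that of dim probe sets, although the values measured for neighbouring genes, single arrays and dim probe sets had not been seen then. Each named gene was examined in each group for 1 array far from the other 9. Of 160 such groups 26 stood out, where chance gives about 8, and 16 of the 26 fell on the arrays numbered 5, 11 in 2x9 and 5 in L2L3M. On 2x9 replicate 5 the lowest value of the group belonged to CALCB (4.38 against a mean of 6.63 for the others, ratio of gap to range 0.701), SPARCL1 (0.639), DHCR7 (0.629), NNT (0.617), ATP5PO (0.615), MPC1 (0.593), IDH3A (11.02 against 11.37, 0.587), MAOB (7.14 against 8.42, 0.551), IVL (0.541), GPI (0.510) and ZNF165 (0.479). On L2L3M replicate 5 the ratio was 0.750 for ATP5PO, 0.641 for SNAI2, 0.623 for GPI and 0.585 for EBP, all lowest, and 0.565 for DDIT3, highest. Without both arrays numbered 5, chosen after seeing the data, 1107 genes were higher and 428 lower, and PPP1R3C, CALCB and MAOB kept their direction and call.

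The other 10 lay on 6 arrays. L2L3M replicate 8 was highest for NDUFS3 (0.517), TNFRSF10B (0.50) and SLC25A5 (0.484). 2x9 replicate 3 was highest for IRF9 (0.509) and OASL (8.66 against 7.61, 0.50). 2x9 replicate 8 was highest for RPS16 (0.60) and, at the floor of 0, lowest for EDDM3B (0.507). 2x9 replicate 10 was lowest for GCM2 (0.623), L2L3M replicate 4 for PPARGC1A (0.495) and L2L3M replicate 2 for RPL8 (0.50).

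Probe sets with no or several symbols were outside the comparison of genes. Of 2491 such probe sets, tested by themselves with limma, 101 were higher and 27 lower in 2x9 at an adjusted p under 0.05, with log2 fold changes of up to 1.67 in size. Of 56 control probe sets without a symbol 0 were called and 7 had an unadjusted p under 0.05.

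More genes rose than fell, with 73.3% of all called genes and 89.0% of those changed at least 1.5-fold higher in 2x9. An offset between arrays left by the normalization would move all genes of a level together, and in 20 bins of genes by level the median log2 fold change lay at most 0.076 from 0, too little for a 1.5-fold change. For the smaller changes an offset stays open: after quantile normalization 59.3% of all called genes were higher, with 666 lower against 406 as deposited. With the array set as a block, which leaves the values as they are, the share also fell, to 63.9%. There, however, more genes were called in each direction than without the block, so that fall does not bear on an offset. Quantile normalization also moved the median log2 fold change over all genes, from -0.010 as deposited to -0.028. The reason for the lower share after quantile normalization is not settled. Noise of dim probe sets would spread both ways, and among genes above the median level the share was 96.3%, with 156 higher and 6 lower. For changes of at least 1.5-fold, that the receptor-binding variant mainly raises transcripts remains a hypothesis, with other differences between the viruses open.

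AURKA, MCM4 and CCNE1 rose in 2x9. A larger share of cycling cells would raise cell cycle genes in general, yet over 21 such genes outside the list and above the bacterial readings the median log2 fold change was -0.052, with quartiles of -0.107 and 0.061, and over all 38 measured, including the dim DLGAP5, which fell, it was -0.033. For MCM4, a probe set reading another transcript would not be joined by its further probe sets, and both rose, by 1.079 and, from within the bacterial range, by 1.359 on the log2 scale. For AURKA this stays open, since of its further probe sets one, an _s_at, rose by 2.37 and the other, at 3.52 in L2L3M and 4.42 in 2x9, read within the bacterial range in both groups and was not called (log2 fold change 0.905, limma adjusted p = 0.0608), and for CCNE1, with 0 further probe sets, it stays open too. A regulatory region shared with neighbours would raise these as well, and 0 of 4 measured neighbours (CSTF1, PRKDC, UBE2V2 and URI1) were called by limma and 0 had an unadjusted p under 0.05; regulation by ERR-alpha was not tested.

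Inflammatory genes were lower in 2x9. Array sets spread unevenly over the groups would bring the median of the list to 0 under a block, and it was -0.22 against -0.20 without the block. The sets held 3, 2, 2 and 3 arrays of 2x9 and 4, 1, 2 and 3 of L2L3M. This near-even spread left the block little to change, so the value under the block adds little. A single array would lift the adjusted p when left out, and the highest camera adjusted p over 20 such fits was 0.000272. A weaker interferon response to the virus would lower the interferon list, whose median was 0.0785 with no member called. The members of that list varied together, with an estimated correlation of 0.575. Its medians within the 4 array sets ran from -0.075 to 0.183. A modest weakening is therefore not excluded. In 1 of 100 splits of the arrays, the real one, camera gave this list a p as small (2.44e-05, against 0.00025 for the smallest of the other splits). Unequal virus dose stays open, as does an effect of ERR-alpha on these genes.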

How the results depend on the processing

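The array set block, the fits without both arrays numbered 5, the fits that leave out 1 array for the inflammatory list and the tests of each probe set by itself were chosen after the data were seen. The block was also drawn from the deviations that it takes out, so calls gained under it may come too easily. Of 15 called lists 12 kept direction and call under every alternative run, and so did 51 of 64 called named genes; 1 named gene turned, COX5A at -0.093 without _x_at and _s_at probe sets, where a dim probe set stands in for it. Where another cause is not given, the cause was not tested. Leaving out each array in turn gave 1017 to 1116 genes higher, 334 to 451 lower, 253 to 274 higher and 27 to 43 lower by at least 1.5-fold, and inflammatory adjusted p from 1.35e-05 to 0.000272. Genes lower numbered 666 after quantile normalization and 795 with the array set block. Without _x_at and _s_at probe sets 613 were higher and 214 lower, with fewer genes tested (8509). At an adjusted p under 0.01, 147 were lower and 15 lower by at least 1.5-fold. Without the lowest 25% of genes 20 were lower by at least 1.5-fold, and without the lowest 50%, 156 were higher and 6 lower by at least 1.5-fold; each probe set by itself gave 51 lower.

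Estrogen receptor targets lost their call with adjusted p of 0.0544 (quantile), 0.0541 (median centring), 0.0921 (mean of probe sets), 0.153 (without _x_at and _s_at), 0.0505 (array weights), 0.052 (without 2x9 replicate 10) and 0.125 (estimated correlation), over a range of 0.00792 to 0.153. Branched-chain amino acid breakdown (0.0658) and redox defence (0.056) lost theirs with an estimated correlation. PPAR targets gained a call at 0.0186 (quantile), 0.0448 (median centring), 0.00255 (without _x_at and _s_at), 0.0494 (trend and robust), 0.0391 (array set block), 0.0485 (without both arrays numbered 5) and 6.62e-05 (fry). The unfolded protein list gained one at 0.00413 (quantile), 0.0448 (median centring), 0.0423 (mean of probe sets) and 0.0442 (trend and robust), and the basal list at 0.018 (quantile), 0.0442 (trend and robust) and 0.00939 (fry). Fry, which does not set a list against other genes, also passed hypoxia (0.00227), cell cycle (0.00104) and endothelial markers (0.0429).

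The numbers were not taken to pair the samples, since not every same-numbered pair of deviations correlated above 0.1: over genes above the median level 8 of 10 pairs did and 2 lay below -0.1, and over all genes 3 did. As a hint from the data that the numbers carry some shared variation, 7 of the 10 fell in the same array set in both groups, where 2.7 would be expected without a relation; 2 of the 2x9 and 3 of the L2L3M arrays correlated best with their own number. A replicate block gave 1194 genes higher (68.2% of calls), 556 lower, 273 higher by at least 1.5-fold and 27 lower, and changed no list's call. In 1 of 100 splits, the real one, as many genes were higher (1113, highest of the others 1), lower (406, 1), or changed at least 1.5-fold (267 and 33, 1). A share of 1 in 100 is the smallest that 100 splits can give, so chance was unlikely for these counts but not excluded. As many lists as the 15 were called in 5 of 100 splits, with up to 19 in another split, so chance is not excluded for that number. Whether a structure of the arrays or an uneven share of the 2 viruses in those splits made lists pass was not tested. With an estimated correlation 1 of 100 splits called as many as the real one (12), and the others called 0. With the preset correlation the smallest camera p for complex I in another split was 1.14e-21 (real 1.40e-32), so p-values with that correlation are not to be read as error rates. Among single lists the real p was matched or passed in 3 splits for redox defence and 5 for estrogen targets. Signal over background limits the dim genes: the median SE of a log2 fold change was 0.30 under a log2 level of 4 and 0.04 at 10 and above. The pseudocount alternatives were not run, since the values were already logs.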

Other observations

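The genes, sets and tests here were all chosen or revised after values were seen. The malate-aspartate shuttle, which carries reducing equivalents into mitochondria, changed almost as a whole. Of its 7 genes 6 rose, with a median log2 fold change of 0.74 (camera p = 1.55e-14, and 0.000168 with an estimated correlation, both unadjusted and on a set picked from these data). GOT1, the cytosolic transaminase, rose by 1.91 ± 0.04 (SE, n = 10 per group), MDH1 by 0.74, and the carriers SLC25A12 and SLC25A11 by 1.26 and 0.87. GOT2 and MDH2 rose by 0.43 and 0.34. SLC25A13, the second aspartate carrier, had a log2 fold change of -0.15 ± 0.06 and was not called.

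Synthesis of coenzyme Q, the electron carrier between respiratory complexes, rose in 8 of 10 measured genes, with PDSS1 at 1.57, COQ9 at 1.40 and COQ3 at 1.20. Beside PPP1R3C, GYS1, the muscle-type glycogen synthase, rose by 0.40 ± 0.06, while the glycogen phosphorylases PYGL and PYGB had log2 fold changes of -0.12 and -0.09 that were not called. BDH1, which interconverts ketone bodies, rose by 2.00, from an L2L3M level of 5.15 within the range of bacterial probe sets, and OXCT1, the enzyme that activates them for use, stood at -0.06. MAOB, also within that range in L2L3M, rose by 3.19 and its relative MAOA stood at 0.01. A scan of 212 families of genes sharing a symbol stem called 10 with camera, 5 of them also with an estimated correlation: the COX, NDUFA, TIMM, NDUFB and ABHD stems. Of 12 ABHD genes, which encode proteins with an alpha/beta hydrolase fold, 7 rose, with ABHD11 at 0.96. Of 12 CXCL chemokine genes 5 fell and none rose (camera adjusted p = 0.00963, and 0.141 with an estimated correlation).

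A hypothesis that genes next to strongly raised ones are drawn along was tested on the 326 measured neighbours, of another family, of 263 genes raised at least 1.5-fold. Of these neighbours, those themselves raised 1.5-fold included, 10.1% were called higher, against a median of 9.94% over 10000 random gene sets of like level (one-sided permutation p = 0.459). No excess beyond chance was found, which does not exclude a small one.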
